A study of Mus musculus with 6 samples.

How the data were processed

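Liver RNA from 6 male mice was measured, 1 mouse per array, in a control group given water by gavage (n = 3) and a group given an aqueous extract of the jujube Ziziphus jujuba (n = 3). Per the labels' protocols, mice were 8 weeks old at day 0, received 500 µl by gavage each day for 20 days, the extract being at 6 mg/mL, and 0.2 µg of RNA was labelled with Cy3 for a 1-colour Agilent array. The submitters' processing notes name Agilent Feature Extraction, and its version is not given in the sources used here. The labels name separate individuals in each group, so n counts mice.

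The values the authors deposited are intensities, 1 per feature and array, for 45220 features, in whole numbers that reach below 0. Their background correction and any scaling between arrays are not given in the sources used here. Median intensities were 3, 3 and 5 on control arrays 1, 2 and 3 and 9, 5 and 8 on extract arrays 1, 2 and 3. The upper quartiles were 41, 41 and 102 in the controls and 99, 123 and 111 in the extract group. Features above 100 numbered 10268, 10308 and 11337 on the control arrays and 11263, 12130 and 11666 on the extract arrays, and 9434 features exceeded 100 on all 6. These are called bright features. The number of arrays limits the precision of every value. The authors also deposited a table of ratios, per the file headers the ratio of each of 3 treated mice to the control average, for 122 genes under 12 functional headings. How those genes were chosen is not given in the sources used here.

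Only these 122 features are paired with a gene name here, and the other 45098 features, control spots possibly among them, stayed unnamed and in the fits. Of the 122 accessions, 111 were found in a RefSeq gene table of assembly GRCm38.p6, all 111 with the symbol of the authors' table. The other 11 kept the symbol of that table. This check sets accession beside symbol only, and whether each feature measures its named gene was not tested. Control mean intensities were, for example, 3731 for the bitter taste receptor gene Tas2r123 and 208 for the fatty acid omega-hydroxylase gene Cyp4a12a. Of 41 gene lists fixed for liver, 7 hold a named gene and none holds the 5 needed for a test. The list tests, and some genes that the naming rule asked for, are therefore not analysed here.

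Because the arrays' medians and quartiles differed by more than 0.1 (log2), intensities were quantile normalized between the 6 arrays, values under 1 were set to 1, the lowest positive value, and log2 was taken. Fold changes of dim features are understated by that floor. Extract and control arrays were compared with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 45220 features and a threshold of 0.05. A count at unadjusted p below 0.01 and at least 1.5-fold was kept beside it. Adjustment over the 122 listed genes alone is given as well, and since the ratios of that list come from these samples it is not independent evidence. For a single gene, 3 against 3 mice give a smallest two-sided exact permutation p of 0.10.

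The ratio of each extract mouse to the control mean was recomputed from the deposited intensities without scaling and set beside the ratio in the authors' deposited table, with 0.005 as the tolerance for equal values. A deposited value was counted as equal to another mouse's at a difference under 1e-08, and as offset by a whole multiple of 0.1 within 1e-06.

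Features were placed on the array by their number, in 532 rows of 85. The row length was read from the data. Deviations of bright features correlated across features 85 numbers apart at 0.335 to 0.498 on the 6 arrays, against medians of 0.0305 to 0.160 over other distances. The local deviation of an array is the median, over a neighbourhood of 11 by 11 features, of each feature's difference from its mean over the arrays, using features above 100 on at least 4 arrays.

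The comparison was tested on simulated data with 200 changed features among the bright ones, 50 at each of 4 fold sizes, over 45220 features. Median estimates were 0.57, 0.96, 1.63 and 2.96 on the log2 scale for true values of 0.58, 1.00, 1.58 and 3.00. The planned fit called 0 of 50 at 1.5-fold, 2-fold and 3-fold and 39 of 50 at 8-fold. A fit of the 9434 bright features called 2, 25, 46 and 49 of 50. With the 200 changes planted, 3 other features were called in the planned fit and 9 in the fit of bright features, and with none planted 0 were called in either. A position trend planted on 1 array was recovered with a correlation of 0.978 and a slope of 0.995.

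Groups, the tests, most alternative settings, the gene lists and the rule for named genes were set before the data were examined. The rule takes genes past the adjusted threshold, fills each direction to 12 genes by the smallest unadjusted p, and adds members of 2 blood pressure lists and of the cell type lists and the 5 highest and 5 lowest entries of the authors' table. The other genes of the cardiovascular heading were added after their values were seen, except 1 that is not reported here. Alternatives covered scaling, filters, the variance model, array weights, the replicate number, an unmoderated test with unequal variances and each array left out. Fits without scaling, on bright features, with local deviations subtracted, and with combinations of these were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.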

Results

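Gene expression was measured in the liver of 6 male mice after 20 days of daily gavage. The control group received water (n = 3) and the treated group an aqueous extract of jujube, a fruit tree whose extracts are taken as infusions (n = 3). The study asks which liver genes respond to the extract and sets that beside its effect on blood pressure, which is not analysed here. Between 22.7% and 26.8% of the 45220 features on an array exceeded an intensity of 100.

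No feature passed the adjusted threshold between extract and control livers. Among named genes, the smallest adjusted p-values belonged to Mrps11, a protein of the small subunit of the mitochondrial ribosome, and Afg3l1, a mitochondrial protease subunit. Normalized Mrps11 was 10.35 ± 0.04 (SD, n = 3) in extract livers and 11.89 ± 0.28 (SD, n = 3) in controls on the log2 scale, a difference of -1.53 (SE 0.19, limma adjusted p = 0.200). Afg3l1 was 8.95 ± 0.15 (SD, n = 3) against 7.76 ± 0.11 (SD, n = 3), a difference of 1.18 (SE 0.15, limma adjusted p = 0.218). All 3 extract mice lay outside the range of the controls for both genes. With trend and robust eBayes on bright features, a setting chosen after seeing the data, both passed, with limma adjusted p = 0.0126 for Mrps11 (0.0126 to 0.739 over alternatives) and 0.0271 for Afg3l1 (0.0271 to 0.739).

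The limma fit gave 0 of 45220 features at an adjusted p below 0.05, with a smallest adjusted p of 0.106. At an unadjusted p below 0.05 there were 2313 features, or 5.11%, and an unmoderated test with unequal variances also gave 0 after adjustment. At unadjusted p below 0.01 and at least 1.5-fold there were 669 features, 240 higher and 429 lower with the extract. Without scaling between arrays the counts were 1209 higher and 67 lower, without extract mouse 1 they were 553 and 378, and on bright features 86 and 69, so the prevailing direction was not the same under every setting. The settings without scaling and on bright features were chosen after seeing the data. In simulated data this fit missed all changes of up to 3-fold, while a fit of bright features, which called 46 of 50 simulated 3-fold changes, also gave 0 in the real data. The simulated noise was independent between features and had no local deviations, so that rate may not hold for the real arrays.

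The genes next in order of p were all higher in each extract mouse than in each control, by values that did not pass the threshold. Xkr5, a member of the XK-related membrane protein family, was higher by 0.92 (SE 0.16, limma adjusted p = 0.377). Gnas, which encodes the stimulatory G protein alpha subunit, was higher by 1.15 (SE 0.23, limma adjusted p = 0.483). The protein kinase gene Dyrk3 differed by 0.94 (SE 0.19) and Cyp4a12a, a male-biased fatty acid omega-hydroxylase, by 0.67 (SE 0.14), each with a limma adjusted p of 0.509. Differences were 0.66 for Psme1, an activator subunit of the proteasome, 0.70 for the anion transporter gene Slc26a11, 0.60 for the nuclear import receptor gene Kpna2, and 0.94 for Cabs1. They were 0.61 for Slc5a1, the sodium-glucose cotransporter SGLT1, 0.69 for Ppnr and 0.71 for the bitter taste receptor gene Tas2r123. Limma adjusted p-values of these 7 genes lay between 0.531 and 0.559. With local deviations on the array subtracted, differences were 0.33 for Cyp4a12a, 0.31 for Kpna2, 0.39 for Psme1 and 0.43 for Tas2r123. They were 1.00 for Xkr5, 0.95 for Cabs1, 0.90 for Gnas, 0.82 for Dyrk3, 0.79 for Slc26a11, 0.57 for Slc5a1 and 0.52 for Ppnr.

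Named genes with lower values in the extract group were few, as 119 of the 122 have mean ratios above 1 in the authors' deposited table. Over all features, 429 were lower and 240 higher at a limma unadjusted p below 0.01 and at least 1.5-fold. Zfp945 differed by -2.09 (SE 0.61, limma adjusted p = 0.799) and lay below the controls in all 3 extract mice, and the difference was -1.46 without extract mouse 1 and -1.51 with local deviations subtracted. Shf differed by -0.91, Zfp54 by -0.72, Ighv1-62-3 by -0.39, Vnn1, a pantetheinase, by -0.37, Fcgr2b, an inhibitory Fc receptor of sinusoidal endothelium, by -0.36 and Gpr165 by -0.07, and for none of these did the groups separate. The SD among extract mice was 2.09 for Shf, 2.14 for Zfp54 and 2.40 for Fcgr2b. Without extract mouse 1 the differences of these 6 genes were positive, at 0.30 for Shf, 0.52 for Zfp54, 0.34 for Ighv1-62-3, 0.23 for Vnn1, 1.03 for Fcgr2b and 0.33 for Gpr165. With local deviations subtracted they were -0.50 for Shf, -0.56 for Zfp54, -0.41 for Ighv1-62-3, -0.098 for Fcgr2b, -0.094 for Vnn1 and 0.036 for Gpr165.

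Genes bearing on blood pressure were compared because the study concerns a hypotensive effect. Prcp, a carboxypeptidase that cleaves angiotensin II, was 8.64 ± 0.25 (SD, n = 3) in extract livers and 7.95 ± 0.23 (SD, n = 3) in controls, and all 3 extract mice were above all controls (difference 0.69, SE 0.21, limma adjusted p = 0.799). Gch1, the first enzyme of the synthesis of tetrahydrobiopterin, a cofactor of nitric oxide synthases, differed by 0.81 (SE 0.50, limma adjusted p = 0.799) with an SD of 0.92 among extract mice. Its normalized value was 10.33 in extract mouse 1 and 8.72 and 8.73 in the others, and without mouse 1 the difference was 0.28. These and Cyp4a12a were the named members of the lists fixed for blood pressure and vascular tone. Of the 7 genes reported from the authors' cardiovascular heading, of which Ahnak, Kif7, Mapk9 and Tpm1 were added after their values were seen, 6 had higher and 1 had lower mean values with the extract. Ahnak differed by 0.67, the hedgehog pathway kinesin gene Kif7 by 0.62 and the kinase gene Mapk9 by 0.59, with all extract mice above all controls. The tropomyosin gene Tpm1 differed by 0.14 and Smtnl2 by -0.53 (-1.06 to -0.20 with 1 array left out), with overlapping groups. None passed the limma threshold. Among all 122 listed genes, 113 had higher means and 83 had all extract mice above all controls. The ratios of that list come from these same samples, so the counts under this heading are not independent evidence of a response. With local deviations subtracted the difference was 0.88 for Prcp, 0.70 for Gch1, 0.56 for Kif7, 0.41 for Ahnak, 0.34 for Mapk9, 0.18 for Tpm1 and -0.50 for Smtnl2.

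**Figure D1:**
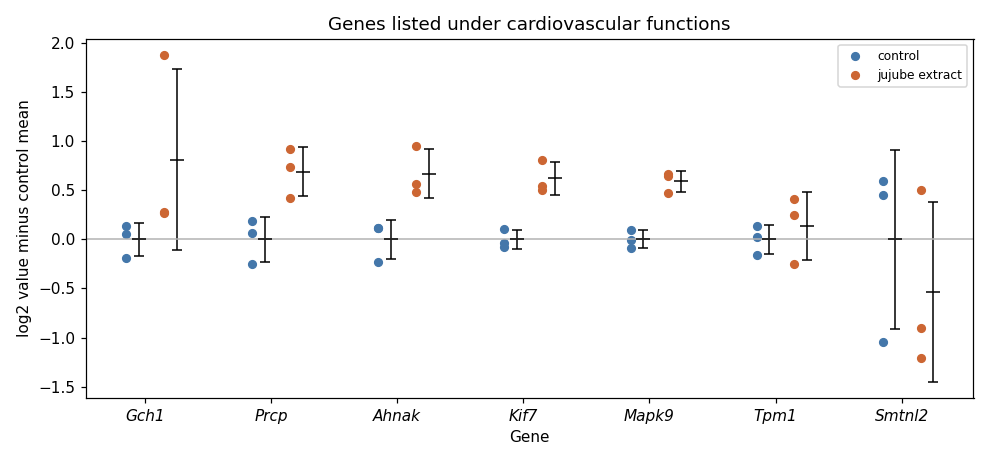
Normalized log2 values of 7 genes under the authors' cardiovascular heading, minus each gene's control mean, for 3 control and 3 extract mice (points), with the mean and SD of each group beside them (bars). Extract mice lie above all controls for Gch1, Prcp, Ahnak, Kif7 and Mapk9, and the groups overlap for Tpm1 and Smtnl2.

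The 122 genes that the authors listed were mostly higher with the extract. Of these, 113 had higher and 9 lower normalized means, and 116 had the direction of the authors' deposited table. The median difference was 0.60 on the log2 scale, or 1.52-fold. All 3 extract mice were above all controls for 83 genes and below for 2, where chance gives 10% of features without overlap for 3 against 3 in both directions together. The ratios of this list come from these same samples, so neither number is independent evidence. At the limma threshold 0 of 122 passed over all features and 2, Mrps11 and Afg3l1, passed when adjusted over the list alone (adjusted p = 0.0314 for each).

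By functional heading, all 14 genes of cell division and proliferation had higher means (median difference 0.64), as did all 8 of cell differentiation (0.61), all 7 of cell adhesion (0.62), all 7 of intracellular transport (0.71), all 3 of the reproductive system (0.65) and all 6 of other functions (0.64). Means were higher for 20 of 21 genes of the nervous system (median 0.58), 15 of 17 of signaling (0.60), 12 of 13 of metabolism (0.57), 12 of 15 of the immune system (0.60) and 2 of 3 of apoptosis and autophagy (0.33). With local deviations subtracted, the medians of these 11 headings lay between 0.17 and 0.79, and were 0.39 for cell differentiation, 0.36 for the reproductive system and 0.17 for apoptosis and autophagy. Of the 122 listed genes, 119 have mean ratios above 1 in the authors' deposited table, and those ratios come from these same samples. The number of higher genes under a heading is therefore not independent evidence of a response of that heading. No gene of any heading passed the threshold over all features. The transport gene Trappc12 had the highest difference of the list, 1.29 (SE 0.33, limma adjusted p = 0.707).

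Ratios in the authors' deposited table were then set beside those recomputed from the intensities. Of 366 ratios, 273 were equal within 0.005 and 93 differed, 59 of them for mouse 1, 3 for mouse 2 and 31 for mouse 3. The recomputed ratios carry no scaling, and the arrays differed in brightness. The median of bright features on extract arrays 1, 2 and 3 was -0.23, 0.33 and 0.14 (log2, relative to the mean of all arrays). On control arrays 1, 2 and 3 it was -0.22, -0.18 and 0.15. Whether brightness accounts for the recomputed ratios that fell short of 1.5-fold was not tested. In 89 of the 93 the recomputed ratio was short of 1.5-fold in the listed direction, and only 2 of the equal ratios were. In 89 of the 93 the ratio in the authors' deposited table lay farther from 1 than the recomputed one. In 18 of the 93, 16 for mouse 1 and 2 for mouse 3, the 2 ratios lay on opposite sides of 1. For Tpm1 in mouse 1 the authors' deposited table gives 1.77 and the intensities give 0.913. For Smtnl2 in mouse 3 they give 0.676 and 1.42. For mouse 1, 20 differing ratios of the authors' deposited table were equal to the ratio of another mouse for the same gene. Another 23 over the 3 mice were offset from the recomputed ratio by a whole multiple of 0.1. For Dis3, the catalytic subunit of the RNA exosome and the entry with the highest mean ratio over the mice, the authors' deposited table gives 3.43 for mouse 1, and the intensities give 0.938, which puts its recomputed mean at 2.27, under the 2.66 of Trappc12. For Prcp it gives 1.70 for mouse 1 in the authors' deposited table and 1.27 from the intensities. For Gch1 the values for mouse 3 are 1.73 in the authors' deposited table and 1.41 from the intensities.

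**Figure D2:**
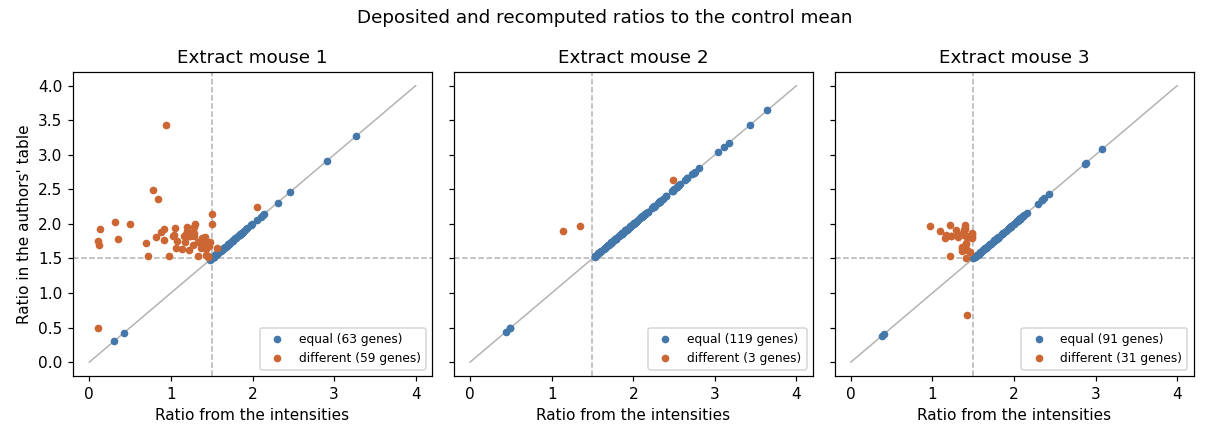
Ratio of each extract mouse to the control mean for the 122 listed genes, as recomputed from the intensities (horizontal) and as given in the authors' deposited table (vertical), with the line of equality and dashed lines at 1.5. Orange points differ by 0.005 or more, 59 for mouse 1, 3 for mouse 2 and 31 for mouse 3, and nearly all lie left of 1.5.

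The table holds 117 genes at 1.5-fold or more above control in every mouse and 2 at the matching decrease, per the authors' deposited table. From the intensities, 41 and 2 of the listed genes met that rule. Trappc12, Afg3l1 and Gnas, among the 5 highest entries, had recomputed ratios equal to the deposited ones, while Dis3 and the transcription factor gene Mef2d did not. Of the 5 lowest entries, Mrps11 and Ranbp3l had equal ratios and Smtnl2, Zfp945 and Mcts1 did not. Mcts1 differed by 0.11 (SE 0.25) and Ranbp3l by 0.55 (SE 0.19) in the limma comparison, and by 0.48 and 0.26 with local deviations subtracted. After quantile normalization 13 of the listed genes met the rule.

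The array of extract mouse 1 stood apart from the rest, and its values enter each gene group above. Over bright features it correlated at 0.955 to 0.959 with the other arrays, which correlated at 0.975 to 0.985 with each other. On that array 307 features lay at least 2 log2 units under the median of the other arrays, against 6 to 101 on the others, Shf, Fcgr2b, Zfp54 and Zfp945 among them. Without it the limma fit called 190 features, 174 higher and 16 lower. With bright features only and local deviations subtracted it called 3 without that array. Xkr5 was among those 3, with a difference of 1.09 (limma adjusted p = 0.0395, over alternatives 0.0395 to 0.958).

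**Figure D3:**
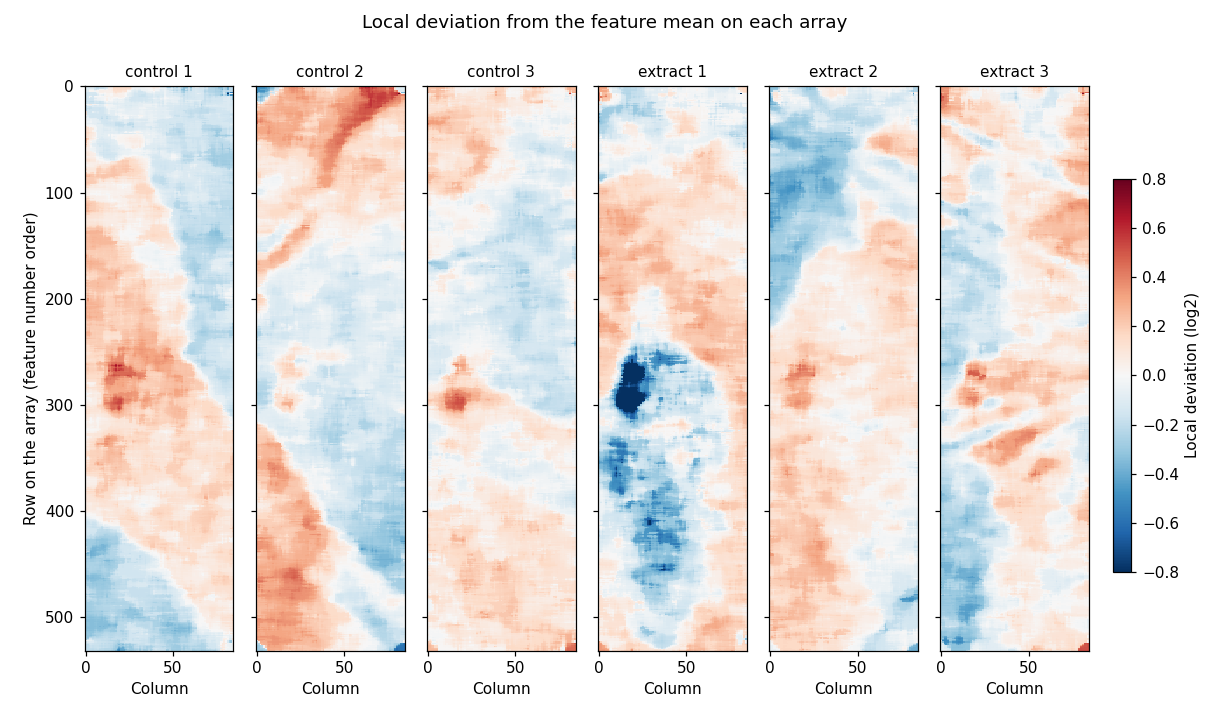
Local deviation (log2) of each of the 6 arrays from the mean of the arrays, by row and column in feature number order, with blue for low and red for high and colours limited to -0.8 and 0.8. The array of extract mouse 1 has a low patch, where the local deviation at bright features reaches -2.05. At bright features the other arrays do not go below -0.59.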

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

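Fits without scaling, on bright features or with local deviations subtracted, and every alternative for the rule of 1.5-fold in each extract mouse, were chosen after seeing the data. The count of 0 features at adjusted p below 0.05 was the same under 16 alternatives. It was 31 without scaling, 4 with trend and robust eBayes on bright features, 3 without extract mouse 1 on bright features with local deviations subtracted, and 0 to 190 when 1 array was left out (190 without extract mouse 1, 41 without extract mouse 3). The 669 features at unadjusted p below 0.01 and 1.5-fold became 359 with trend and robust eBayes, 1276 without scaling, 1019 with the 75th percentile of bright features, 155 on bright features, 91 on bright features with local deviations subtracted, 181 with trend and robust eBayes on bright features, 116 without extract mouse 1 on bright features with local deviations subtracted, 1953 at unadjusted p below 0.05, and 783 to 1154 with 1 array left out (1154 without control mouse 3). With the unmoderated test with unequal variances the count was 207, 77 higher and 130 lower. Of the 1019, 938 were higher and 81 lower. Of the 931 without extract mouse 1, 553 were higher. The replicate block gave 0 and 454 features. Same-numbered mice correlated at 0.04, 0.15 and 0.25 in their deviations from the group means, and the other pairs at -0.19 to 0.03. A batch shared by replicate number is therefore not excluded. The main fit was set without a block before the data were examined. The cause of the changes in these counts was not tested.

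Of the 122 listed genes, 116 kept the listed direction, 113 to 122 with 1 array left out, but 14 with median centring and 17 with 75th percentile centring. Both lowered the median extract-minus-control difference of bright features by construction, to -0.82 and -0.81, and values of single genes under them carry that shift. With the 75th percentile of bright features 117 kept the direction, Prcp at 0.75 and Ahnak at 0.70 among them. The 43 listed genes at 1.5-fold in every mouse became 13 with quantile normalization, 17 with the 75th percentile of bright features, 11 with local deviations subtracted, and 30 to 89 with 1 array left out (89 without extract mouse 1).

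With median centring, negative differences were -0.73 for Mcts1, -0.31 for Ranbp3l, -0.58 for Tpm1, -0.14 for Ahnak, -0.095 for Prcp, -0.021 for Gch1, -0.18 for Mapk9, -0.24 for Kif7, -0.16 for Ppnr, -0.15 for Tas2r123, -0.24 for Slc5a1, -0.13 for Psme1, -0.12 for Cyp4a12a, -0.0055 for Dis3, -0.082 for Slc26a11 and -0.16 for Kpna2. With 75th percentile centring they were -0.72 for Mcts1, -0.30 for Ranbp3l, -0.58 for Tpm1, -0.14 for Ahnak, -0.088 for Prcp, -0.014 for Gch1, -0.18 for Mapk9, -0.23 for Kif7, -0.16 for Ppnr, -0.15 for Tas2r123, -0.23 for Slc5a1, -0.13 for Psme1, -0.12 for Cyp4a12a, -0.075 for Slc26a11 and -0.15 for Kpna2. Gpr165 was 0.14 with array weights, 0.27 without scaling, 0.12 with the 75th percentile of bright features and 0.036 with local deviations subtracted. Fcgr2b was 0.16 with array weights. With 1 array left out, differences ranged from -1.64 to 0.30 for Shf, -1.20 to 1.03 for Fcgr2b, -0.85 to 0.34 for Ighv1-62-3, -0.89 to 0.23 for Vnn1, -0.33 to 0.33 for Gpr165, -1.38 to 0.52 for Zfp54, each highest without extract mouse 1, and from -0.054 to 0.34 for Mcts1 and -0.00044 to 0.34 for Tpm1. On bright features with local deviations subtracted and without that mouse, Vnn1 was 0.40 and Zfp54 0.49. A mean over probes was not run, as each named gene has 1 feature, and neither were the gene list tests.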

Other observations

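Only the test of ratios taken from another feature was set before its result was seen. The tests of brightness, position, the damaged area, clustered spots, the correlation gap and the splits were chosen after the results, or the low patch on the array of extract mouse 1, had been seen.

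The listed genes had higher values with the extract, with a median difference of 0.604 after quantile normalization and 0.457 after local deviations were subtracted, and neither value was taken to decide on array brightness or array position. Of the 122 genes, 117 are at least 1.5-fold higher in every mouse and 2 at the matching decrease in the authors' deposited table, from which it is inferred, without a test, that the genes may have been picked on these samples for such ratios. Over all features with a control mean above 100, 95 were at least 1.5-fold higher and 24 lower in every extract mouse without scaling. The excess of higher features was turned round with quantile normalization (31 higher and 86 lower, 26.5% higher). It was small with the 75th percentile of bright features (47 and 45, 51.1% higher). Under quantile normalization lower features outnumbered higher ones in each of the 20 ordered assignments of the arrays. The turn therefore cannot decide whether brightness accounts for the excess. Selection and an effect of the extract both stay open. Of the 20 ordered assignments of the 6 arrays 13, the real one included, gave at least as many features as the real 119, the highest other 703. All 10 with extract mouse 1 among the controls gave 180 or more, against 29 to 149 and a single 703 with it among the extract arrays. In bright features, control arrays 1 and 2 and extract array 1 were the dimmest, at -0.22, -0.18 and -0.23 (log2, relative to all arrays). The 703, and the 677 of the reverse assignment, set these against the other arrays, and were 90 and 240 with quantile normalization. The count without scaling thus largely follows the array of extract mouse 1 and, at its highest values, array brightness. It was not taken to measure chance.

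The deposited ratios that differ from the intensities were weighed against damage on the array and ratios taken from another feature. The array of extract mouse 1 was locally lower at the differing genes than at the other listed genes, by -0.219 in the median (-0.0407 and 0.179, permutation p = 1e-05). The difference is as large as the damage was taken to need, but it cannot decide, because nearly all genes short of 1.5-fold differ, which by itself selects low places on that array. The median at the differing genes is small beside the SD of local deviations on that array, 0.229. Only 4 listed genes lay at least 2 log2 units under the other arrays there, all 4 with differing mouse 1 ratios. These values argue against a strongly low patch for most of the 59 differing mouse 1 ratios. Of the differing ratios, 10.8% equal the ratio of some other feature for the same mouse within 1e-08, close to the 9.16% of equal ratios that do so by coincidence. Of the 93 differing ratios, 20 equal another mouse's ratio for the same gene and another 23 are offset by a whole multiple of 0.1. Some others repeat the recomputed digits with a digit left out, such as 1.54039 for 1.454039 (Msi1) and 1.84803 for 1.184803 (Gins4), both for mouse 1. Neither damage on the array nor the ratio of another feature would by itself give such values, which argues against both for these ratios. Why they differ, and how the rest were made, stays open, and no biological explanation was tested.

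The array of extract mouse 1 correlated less with the others than they did with each other. A smooth position trend as the whole cause is argued against by the gap in mean correlation, 0.0243 before and 0.0183 after local deviations were subtracted. Of its 307 low features, 38.4% had another low feature next to them, against at most 12.1% in 1000 shuffles of positions, consistent with a loss of signal in patches of the array. A response of that mouse alone was not tested, and it would not follow the position of features on the array.

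The 10 splits of the 6 arrays are too few for a share under 0.05. For features at adjusted p below 0.05 all 10 splits gave as many as the real 0, the highest other giving 0. For the 669 features at unadjusted p below 0.01 and 1.5-fold, 3 of the 10 splits gave as many, the highest other 770. On bright features with local deviations subtracted, 1 of the 10 splits gave as many as the real 91, the real split itself, and the highest other gave 38. At a limma adjusted p below 0.05 in that fit, the real split gave 0 features and the highest other gave 1.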
